A study of Homo sapiens with 2 samples.

How the data were processed

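Small RNA sequencing was compared between untreated MCF10A cells and MCF10A cells given withaferin A at 2 µM for 24 h. The series holds 1 sample record per group, and each record's labels name 3 replicates, which are separate columns of the tables, so n = 3 libraries per group. The column names do not state the treatment, so their assignment to groups rests on the sample names listed in each record. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Per the labels' protocols, 2 kits were used, the QIAseq miRNA Library Kit and the NEBNext Multiplex Small RNA kit. Read in the order given there, QIAseq made the untreated libraries and NEBNext the withaferin A libraries, so kit and treatment cannot be told apart by any covariate.

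The deposited table of counts holds whole numbers for 947 loci in the 6 libraries. Per the submitters' processing notes, Trim Galore, cutadapt and edgeR were used, with no versions, and the genome build was GRCh38.p7. The aligner, the way loci were found and the counting rule are not given, nor is any use of molecular identifiers. A locus is named in the table by its chromosome and a running number, and 450 of the 947 also carry a miRNA name. Of these names 364 end in 5p, 11 in 3p and 75 carry no arm. Many miRNAs whose 3p arm is usually the abundant one are listed only as 5p, so a locus name may stand for a whole hairpin rather than for the arm it states. Reads of miRNAs with several gene copies appear at each copy. Of 237 loci with at least 50 counts in each untreated library, 46 had untreated counts equal to those of another locus, with no tolerance. The 53 names found at more than 1 locus are thus not independent measurements.

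The second table holds the authors' normalized values, a scaled score rather than a count. Within each library it equals the count times 1 factor, rounded to a whole number, and 660 of the 947 loci have values. These were exactly the loci above 0.5 CPM (counts scaled to one common library total) in at least 3 libraries. The factors were proportional to edgeR's trimmed mean of M values (TMM) scaling of those loci. In the authors' score 1 count was worth 698.0, 729.0 and 780.0 units in the withaferin A libraries and 0.451, 0.462 and 0.619 units in the untreated libraries. The score served only for an alternative test, limma on log2(score + 1).

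Totals were 2571073, 2615684 and 1855838 counts in the untreated libraries and 418, 430 and 340 in the withaferin A libraries. Shares are percent of a library's total, given as mean ± SD. List shares sum 1 locus per name over the full total, in which copies that share reads are counted more than once, so they are understated. The chromosome 22 copy of let-7a-5p, left out of the sums, held a mean of 33420 CPM in untreated and 187030 CPM in withaferin A libraries. For ratios of shares, the 3 withaferin A libraries were summed to 1188 counts and exact Clopper-Pearson 95% limits were taken. A locus with 0 of 1188 counts could hold up to 0.253% of counts (3 counts, 2525 CPM), and this level over the group is the floor used for every lower bound on a fold. Intervals and floors cover counting error only. Chi-square tests of counts at 1 locus per hairpin name gave 1.29 to 1.57 per degree of freedom between pairs of withaferin A libraries. Monte Carlo permutation p, Holm-adjusted over the 3 pairs, was 0.0758, 0.0758 and 0.0081, and 0.0099 for the last with the miR-320 names, which share reads, merged. Other shared reads were not tested. Untreated pairs gave 43.9 to 135.9 at full depth and 0.965 to 1.15 thinned to 260 counts. All 3 columns of each group were kept as replicates.

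Loci were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, TMM scaling, filterByExpr with a minimum count of 10, Benjamini-Hochberg adjusted p under 0.05), which left 303 loci. TMM factors were 0.688, 0.668 and 0.707 in the untreated libraries and 0.767, 1.21 and 3.32 in the withaferin A libraries. The SE given with an edgeR log2 fold change is its absolute value divided by the square root of the F statistic. It is derived from the test and is not a separate model estimate. Fixed miRNA lists were tested with camera from limma 3.58.1 with a preset correlation of 0.01, 1 locus per exact name, for lists with at least 3 tested members. Camera ranks a list against the other loci, so its direction is relative to them. The share of the 10 most abundant loci and the number of loci detected at 340 counts were compared with exact two-sided permutation tests, which for 3 against 3 cannot give p under 0.1.

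The lists, the edgeR, camera and exact permutation tests and the rule for named miRNAs were fixed before the data were examined. The rule took up to 12 rises and 12 falls with the largest fitted change among called loci with a mean of at least 100 CPM and no overlap between groups, the 5 most abundant loci of each group, and up to 4 abundant members of each list. let-7e-5p, let-7g-5p and the miR-320 loci fall outside it and are named after their values were seen. Alternatives were other scaling (RLE, library totals), other filters, DESeq2 1.42.0, limma-voom, limma on the authors' score, a test against a fold of 2, a replicate block and leaving out each library. Analyses with 1 locus per miRNA name, with loci above the floor only, and with lists matched by hairpin name were added after seeing the data. So were the exact binomial test of withaferin A counts against the untreated share (counting error) and the comparison with dilution.

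Hairpin positions are from GENCODE 29 on GRCh38, given where exactly 1 hairpin gene of that name lies on the locus's chromosome. The edgeR step was tested on simulated tables of the same 947 loci and library totals. With no locus changed it called 0.4 loci per table on average. With 200 changed loci it called 75.9% of tested loci above the floor set 16-fold lower, 55.0% of those set 4-fold lower, 98.0% of those set 16-fold higher and 11.3% of those set 4-fold higher. It also called 8.98% of unchanged loci above the floor. The simulated loci were drawn independently at a dispersion of 0.06, without shared reads or the composition seen after withaferin A. These rates may thus not hold for the real table.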

Results

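The series asked which microRNAs (miRNAs), the short RNAs that repress matching messenger RNAs, differ after withaferin A in MCF10A cells. MCF10A is a non-tumorigenic human breast epithelial line, and withaferin A is a steroidal lactone from the plant Withania somnifera. Small RNA libraries were made from untreated cells (n = 3) and from cells given 2 µM withaferin A for 24 h (n = 3). The labels' protocol names 2 library kits, and read in the order given there, each group had its own. The groups differed most in depth. Untreated libraries held 1855838 to 2615684 counts (mean 2347532 ± 426403, SD, n = 3), and withaferin A libraries held 340 to 430 (mean 396 ± 48.9, SD, n = 3), a ratio of means of 5928. Between 801 and 841 loci had a count in an untreated library, against 26 to 33 in a withaferin A library. Over the 3 withaferin A libraries together, 44 loci had a count. Of the 52 loci whose untreated mean lay above the level that 3 of 1188 counts allow (2525 CPM, the floor), 28 had a count after withaferin A and 24 had none. For 894 loci the untreated mean was at or below that level, so a count of 0 after withaferin A cannot show a fall there; 16 of them had a count after withaferin A. The files give no read totals before trimming and counting, so these totals are counted reads and not the sequencing depth.

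**Figure D1:**
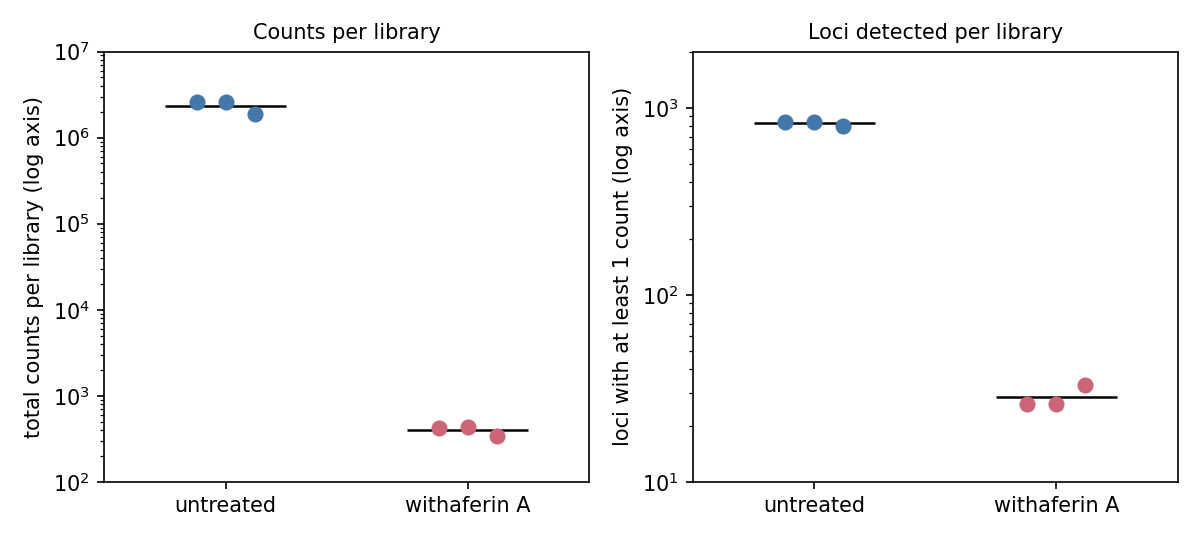
Total counts (left) and loci with at least 1 count (right) per library, both on log axes. Each point is 1 library and each line the mean of 3. The withaferin A libraries hold 340 to 430 counts and the untreated libraries at least 1855838.

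The leading miRNAs of the 2 groups were not the same. In untreated cells miR-21-5p, often raised in carcinomas, took 29.4% ± 2.34 of counts (SD, n = 3), and it took 2.49% ± 0.676 after withaferin A (29 counts). Its share was 12-fold lower (exact 95% limits 8.43 to 17.9). miR-21-5p fell in edgeR with a log2 fold change of −4.71 ± 0.54 (SE, adjusted p = 0.00188), lower in 3 of 3 libraries, and it passed the test under every alternative run (−6.16 to −3.58). Its hairpin lies on chromosome 17 at 59841266 to 59841337, overlapping an exon of VMP1. miR-205-5p, a miRNA of basal and stratified epithelia, took 6.82% ± 0.588 of untreated counts and 32.9% ± 4.20 after withaferin A (395 counts). That share ratio of 4.88 (exact 95% limits 4.48 to 5.28) was a log2 fold change of 1.44 ± 0.58 after TMM scaling, which did not pass (edgeR adjusted p = 0.16). It passed with library totals (2.28, adjusted p = 0.000344) and with loci above the floor only (2.54, adjusted p = 0.0179). It was 0.22 with RLE factors and in DESeq2, and turned below 0 without untreated replicate 1 (−0.21) or 2 (−0.31). Those leave-out fits kept only 10 loci, with totals and scaling recomputed on them. The effect of the missing library and that of the smaller table cannot be told apart there. The miR-205-5p hairpin lies on chromosome 1 at 209432133 to 209432242, in an exon of MIR205HG. The ratio of miR-205-5p to miR-21-5p counts was 0.232 (0.228 to 0.237 over libraries) in untreated cells and 13.6 (8.91 to 17.1) after withaferin A.

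Members of the let-7 family, which share a seed sequence and are known as repressors of growth genes, did not move together. let-7c-5p rose, from 0.870% ± 0.154 to 8.09% ± 2.32 of counts (97 counts, log2 fold change 2.39 ± 0.62, edgeR adjusted p = 0.0311), higher in 3 of 3 libraries. It no longer passed against a fold of 2 (adjusted p = 0.0804), without untreated replicate 1 (0.79, adjusted p = 0.174) or 2 (0.81, adjusted p = 0.0506), or without withaferin A replicate 1 (1.02, adjusted p = 0.0877). Fits without an untreated library kept only 10 to 12 loci, with scaling recomputed on them, so they differ from the main fit by more than that library. The let-7c-5p hairpin is on chromosome 21 at 16539828 to 16539911, in an intron of MIR99AHG. let-7a-5p, counted at near-equal values at its copies on chromosomes 11 and 22, went from 3.34% ± 0.859 to 19.5% ± 1.45 at the chromosome 11 copy. Over the 303 loci with TMM it did not pass (1.69, edgeR adjusted p = 0.099). It passed with library totals (2.54, adjusted p = 0.000545), with loci above the floor only (2.82, adjusted p = 0.007), with 1 locus per name (0.79, adjusted p = 0.0284) and in limma-voom (adjusted p = 0.034). Without 1 of the untreated libraries it was 0.07 to 0.24, again over only 10 to 12 loci. With RLE factors (0.47, adjusted p = 0.374) and in DESeq2 (0.47, adjusted p = 0.336) let-7a-5p did not pass. let-7f-5p was called lower (−2.16 ± 0.44, edgeR adjusted p = 0.0155), from 4.61% ± 0.931 to 2.48% ± 1.45. It did not pass with library totals (−0.94, adjusted p = 0.257) or with loci above the floor only (−1.20, adjusted p = 0.059). let-7g-5p had a larger fitted fall (−4.77, edgeR adjusted p = 0.0133, 2 counts against 22.7 expected from the untreated share). With library totals let-7g-5p did not pass (−3.50, adjusted p = 0.0739). let-7i-5p was also called lower in edgeR (−2.06, adjusted p = 0.0311), but it did not pass with library totals (−0.83, adjusted p = 0.61), with loci above the floor only (adjusted p = 0.059) or against a fold of 2 (adjusted p = 0.0929), and its 15 counts lay within counting error of the untreated share (exact binomial test, adjusted p = 0.134). The ratio of let-7a-5p to let-7f-5p counts was 0.730 (0.675 to 0.758) in untreated libraries and 8.29 (4.43 to 13.7) after withaferin A. No library scaling can alter these within-library ratios.

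**Figure D2:**
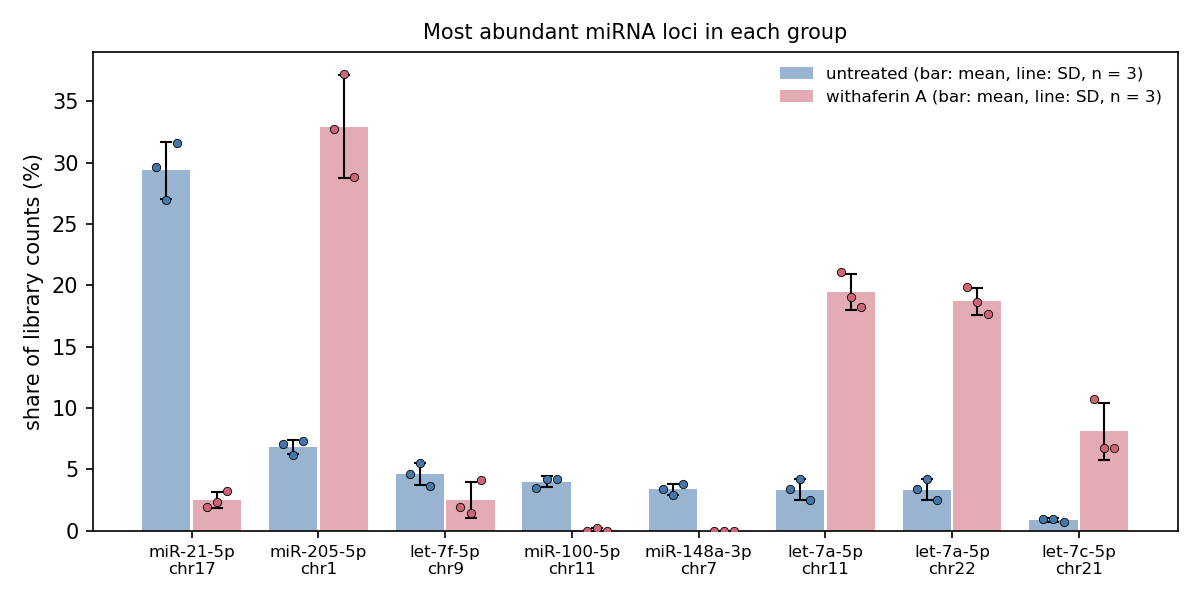
Share of library counts (%) for the 8 loci that were among the 5 most abundant of either group. Bars are means, lines SD and points single libraries (n = 3 per group). miR-21-5p goes from 29.4% to 2.49% and miR-205-5p from 6.82% to 32.9%.

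The largest fitted falls were at loci with 0 counts in all 3 withaferin A libraries, so each fold is a lower bound. miR-148a-3p, 3.36% ± 0.454 of untreated counts (SD, n = 3), was at least 13.3-fold lower. Its hairpin on chromosome 7 at 25949919 to 25949986 lies in no annotated host gene. The locus named miR-148a-5p, on the same hairpin with 3.29% of untreated counts, was at least 13.0-fold lower, and near-equal counts leave open whether the arms were counted apart. miR-378a-5p, from an intron of PPARGC1B, was at least 3.50-fold lower, miR-27a-5p at least 3.42-fold and miR-20a-5p, of the miR-17/92 cluster, at least 3.36-fold. For miR-30a-5p, miR-151b, miR-200c-5p, miR-222-5p, miR-29a-5p, miR-17-5p and miR-26b-5p the bounds ran from 2.77-fold down to 1.91-fold. The shares gained by miR-205-5p, let-7a-5p and let-7c-5p would alone make every other locus 4.22-fold lower. Of these 12 loci, only miR-148a-3p and miR-148a-5p had exact 95% intervals wholly below that level. For the others a fall beyond such dilution was not shown. edgeR adjusted p for these 12 loci ran from 0.00289 to 0.0311. With library totals in place of TMM 5 of the 12 passed and the 7 with bounds of 2.77-fold or less did not (adjusted p = 0.0551 to 0.179). Of the 7, miR-17-5p and miR-26b-5p lay within counting error of the untreated share (exact binomial test, adjusted p = 0.0555 and 0.0527). miR-100-5p, 3.96% ± 0.446 of untreated counts, had 1 count after withaferin A, a 47.1-fold lower share (exact 95% limits 8.47 to 1860), and fell (−6.80 ± 0.77, edgeR adjusted p = 0.00188). It is made from an intron of MIR100HG, on chromosome 11 at 122152229 to 122152308.

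Across the 303 loci tested in edgeR, 53 were called, 2 higher and 51 lower. The higher ones were let-7c-5p and an unnamed locus on chromosome 16, which went from 16.7 to 18348 CPM (10, 2 and 9 counts, log2 fold change 8.89 ± 0.78, adjusted p = 0.000704). Of the 51 lower, 18 had a count after withaferin A and 33 had none, and 9 of those 33 lay at or below the floor in untreated cells, so that no fold can be given. Of the 53, 51 carried a miRNA name, which made 40 distinct names with gene copies and arms merged. With library totals in place of TMM, 17 were called, 6 higher (let-7a-5p at 2 loci, let-7c-5p, let-7e-5p, miR-205-5p and the chromosome 16 locus) and 11 lower, with 13 of the 53 among them. limma-voom called 234 (180 higher), limma on the authors' score 631 of 660 (2 higher), and edgeR without 1 of the untreated libraries 6 to 9 of the 10 to 12 loci it then tested. The exact binomial test of summed withaferin A counts was chosen after the results were seen and ignores spread between libraries. It put 31 of the 303 loci outside counting error (adjusted p under 0.05), 9 with a higher share and 22 with a lower share. The 9 were the chromosome 16 locus, let-7c-5p, let-7a-5p and miR-16-5p at 2 loci each, let-7e-5p, miR-205-5p and miR-125a-5p.

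**Figure D3:**
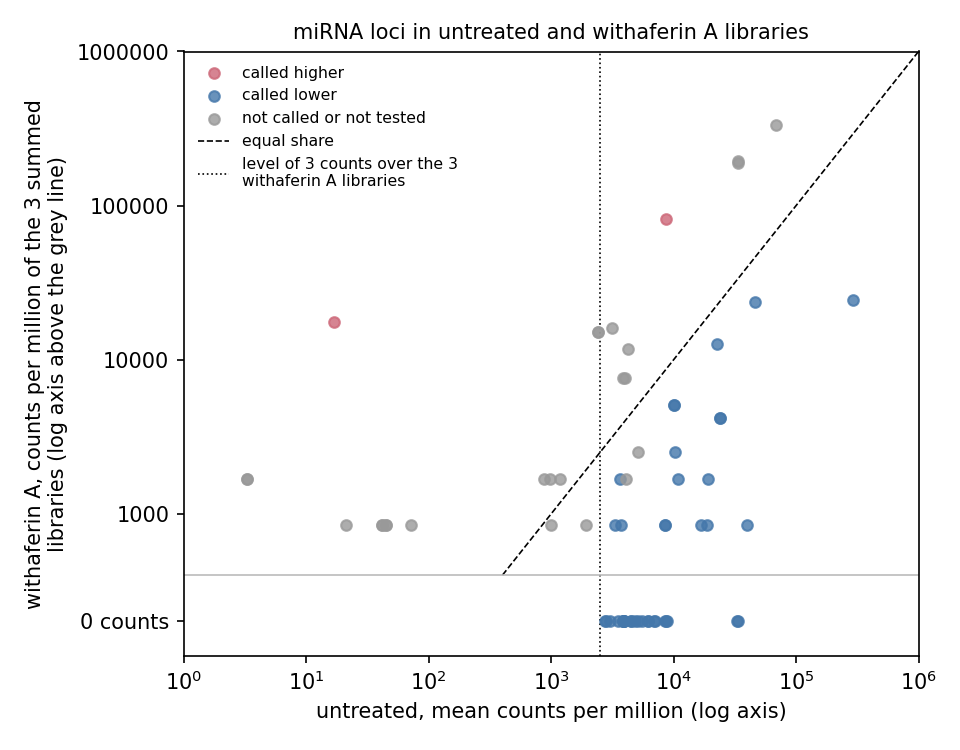
Untreated mean CPM against CPM of the 3 summed withaferin A libraries, on log axes, for loci above the floor (dotted line, 2525 CPM) or with a withaferin A count. Points are loci, colours the edgeR call, the dashed line equal shares. The 24 loci in the bottom strip had 0 counts after withaferin A, and the 9 called loci at or below the floor are not drawn.

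Among the fixed lists, every member tested of the miR-23/27/24 clusters was called lower (5 of 5, and 5 adjusted over the list alone). Their summed share went from 4.44% ± 0.0394 to 0.331% ± 0.350 (SD, n = 3). All 5 lay above the floor, where 42 of the 52 loci were called lower in edgeR. camera did not set these clusters apart from other loci (adjusted p = 0.879 in limma). miR-27b-5p (−5.73, edgeR adjusted p = 0.00289, 1 count) and miR-24-3p (−3.28, adjusted p = 0.0124, 3 counts) were members. Of the miR-30 family 4 of 5 were called lower (5 adjusted over the list alone), among them miR-30d-5p (−5.56, edgeR adjusted p = 0.00474, 1 count). The family's share went from 3.28% ± 0.651 to 0.0797% ± 0.138. Its 4 called members were the 4 above the floor, and camera did not set the family apart either (adjusted p = 0.879 in limma). With a replicate block in edgeR, miR-24-3p, miR-24-2-5p and miR-30e-5p (adjusted p = 0.054 each) and miR-30c-5p (adjusted p = 0.0827) were not called. In the set of miRNAs known to promote breast cancer, 5 of 8 were called lower and 3 did not pass (6 adjusted over the list alone), but 2 of the 5 had 0 counts and an untreated mean at or below the floor, where no fall can be shown. Its share went from 31.8% ± 2.62 to 3.08% ± 0.849, most of it miR-21-5p, and miR-182-5p (−2.50, edgeR adjusted p = 0.0727) did not pass with TMM but was called lower with RLE factors (adjusted p = 0.00122) and in DESeq2 (adjusted p = 0.00733). The 2 counts of miR-182-5p lay within counting error of the 4.88 expected from the untreated share (exact binomial p = 0.255). The miR-17/92 cluster and paralogs had 3 of 7 lower (4 adjusted over the list alone), miR-20a-5p, miR-17-5p and miR-93-5p (−3.22, edgeR adjusted p = 0.0457, 1 count), the last not called with library totals (adjusted p = 0.384) or against a fold of 2 (adjusted p = 0.0929). The miR-181 family had 2 of 3 called lower (1 of them, miR-181b-5p, at 0 counts and at or below the floor in untreated cells), the miR-29 family 1 of 3, the miR-200 family 1 of 2, the NF-kB-linked list 1 of 6 (miR-21-5p) and the hypoxia and oxidative stress list 1 of 4 (miR-93-5p), with the same counts adjusted over the list alone. With library totals edgeR called 2 lower in the miR-23/27/24 clusters and 1 each in the miR-30, cancer-promoting, miR-17/92 and NF-kB-linked lists. It then called 0 in the miR-181, miR-29, miR-200 and hypoxia lists (2, 1, 1 and 0 at an unadjusted p under 0.05), where DESeq2 called 2, 1, 1 and 1 lower. limma-voom called 3 miR-17/92 members higher and 3 lower. Of the edgeR calls, 2 in the miR-23/27/24 clusters, 2 in the miR-30 family, 3 in the cancer-promoting list, 2 in the miR-17/92 cluster (miR-17-5p and miR-93-5p), 2 in the miR-181 family and 1 in the hypoxia list lay within counting error of the untreated share (exact binomial test, adjusted p of 0.05 or more), so depth and a fall cannot be told apart there.

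In the let-7 family 1 of 7 was called higher, 3 were called lower and 3 did not pass (6 passed adjusted over the list alone). With library totals 3 were called higher and 0 lower, while the family's summed share went from 13.4% ± 3.68 to 33.1% ± 3.01 (SD, n = 3). camera placed the family above other loci (adjusted p = 6.53e-07 in limma, adjusted p = 0.23 with an estimated correlation, and 0.332 to 0.417 without 1 of the untreated libraries, when 3 members were tested), although its median fitted log2 fold change was −2.06. The tumour suppressor list had 0 of 12 higher and 3 lower (3 adjusted over the list alone, and 1 higher and 1 lower with library totals), miR-26a-5p (−3.69, edgeR adjusted p = 0.0155, 5 counts), miR-26b-5p, which lay within counting error, and miR-30a-5p. Its share went from 11.6% ± 0.767 to 35.6% ± 4.28, most of it miR-205-5p, which is also in the basal epithelial list. camera placed it above other loci too (adjusted p = 0.00996 in limma, adjusted p = 0.23 with an estimated correlation, and 0.47 without withaferin A replicate 2), while its median fitted change was below 0. The other 12 lists tested had camera adjusted p from 0.166 to 0.879 in limma. In the basal epithelial list 0 of 5 passed in edgeR, 2 at an unadjusted p under 0.05, and its share went from 7.15% ± 0.554 to 33.1% ± 4.43. DESeq2 called 1 of its members lower, and edgeR with library totals 1 higher. The p53-responsive list had 0 of 6 called in edgeR, 1 at an unadjusted p under 0.05 and 0 in DESeq2, and miR-34a-5p had 2 counts (−0.71, edgeR adjusted p = 0.79). The miR-15/16 family had 0 of 4 called in edgeR, 0 at an unadjusted p under 0.05 and 0 in DESeq2. Its member miR-16-5p took 0.242% ± 0.161 of untreated counts and 1.53% ± 0.496 after withaferin A (edgeR adjusted p = 0.26). Its 18 counts, against 2.88 expected from the untreated share, lay outside counting error (exact binomial test, adjusted p = 4.77e-08). limma-voom called 1 basal epithelial member higher and 1 lower, and 2 p53-responsive and 3 miR-15/16 members higher.

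Lists of miRNAs from other cell types were low in untreated cells and had 0 counts after withaferin A, which allows up to 0.253% each. Mesenchymal and stromal miRNAs took 0.00497% ± 0.000441 of untreated counts (SD, n = 3), blood cell miRNAs 0.00887% ± 0.00268 and liver and muscle miRNAs 0.00589% ± 0.00205. Entries thought to be fragments of other RNAs took 0.0995% ± 0.00817. In edgeR 0 of their 7 tested loci were called, 1 at an unadjusted p under 0.05, against 1 lower in DESeq2 and 6 higher in limma-voom.

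How counts were spread over loci was compared with 1 value per library. The 10 most abundant loci took 63.2% ± 0.540 of untreated counts and 91.4% ± 4.30 of withaferin A counts (SD, n = 3), a difference of 28.2 percentage points (exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows). With every library thinned to 340 counts, 67.0 ± 1.74 loci were detected in untreated libraries and 26.9 ± 5.32 after withaferin A (n = 3, exact two-sided permutation p = 0.1). The libraries of the 2 groups did not overlap in either measure. Neither comparison can pass 0.05 in this design.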

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

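The analyses with 1 locus per miRNA name, with loci above the floor only and with lists matched by hairpin name were chosen after seeing the data. The count of called loci (53, of which 2 higher and 51 lower in edgeR) was 17 (6 and 11) with library totals only. It was 234 (180 and 54) in limma-voom, 631 (2 and 629) in limma on the authors' score, where 1 count in a withaferin A library is worth at least 698.0 units, and 25 (1 and 24) with a replicate block. It stayed within 1.5 times with RLE factors (66), no filter (51, of which 4 higher), at least 10 CPM (53), DESeq2 (71, of which 5 higher, with 697 loci given no adjusted p), a fold of 2 (40, of which 1 higher), 1 locus per name (57, of which 3 higher) and loci above the floor (44, of which 5 higher). Leaving out 1 library gave 6 to 59 called, 1 to 4 higher and 5 to 55 lower. The low end came without an untreated library, where the count filter, set by the median library, kept 10 to 12 loci. Upper-quartile factors could not be computed, since that quantile was 0. For the other changes the cause was not tested.

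The 2 lists called by camera became 0 with an estimated correlation and 1 with loci above the floor, and 0 to 2 when 1 library was left out. The 0 came without an untreated library, with 1 list left to test. The difference in the share of the 10 most abundant loci (28.2 points) and in loci detected at 340 counts (−40.1) kept its sign under every alternative run. They shrank to 3.55 points for the 1 most abundant locus (exact permutation p = 0.3), −4.76 loci at 5 counts or more, and 24.0 points and −30.0 loci with 1 locus per name.

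The 59 named loci gave 822 comparisons with the alternatives. In 702 the direction and the side of the threshold stayed, in 48 a call was gained, in 36 lost, and in 26 the sign changed with no call on either side. limma-voom reversed 10, all with 0 counts after withaferin A, where its offset for a 0 in a small library gives a higher value. Their log2 fold changes there were 5.48 for miR-199a-5p and miR-199b-5p, 2.95 for miR-486-5p, 3.58 for miR-122-5p, 3.85 for miR-210-5p, 3.17 for miR-15a-5p, 4.99 for miR-424-5p, 4.48 for miR-181d-5p, 4.10 for miR-664a-5p and 5.07 for miR-619-5p. let-7c-5p lost its call against a fold of 2 (adjusted p = 0.0804), with the block (0.0667), without untreated replicate 1 (0.174) or 2 (0.0506) and without withaferin A replicate 1 (0.0877), in a range of 8.18e-05 to 0.174. With the block 9 named loci lost their call, let-7c-5p among them. The others were let-7f-5p (adjusted p = 0.0827), let-7i-5p (0.152), miR-93-5p (0.265), miR-24-3p, miR-24-2-5p and miR-30e-5p (0.054 each), miR-30c-5p (0.0827) and miR-181b-5p (0.173). Deviations of equal replicate numbers correlated at 0.0526, −0.0045 and 0.0772 across loci, and not every library correlated best with its own number. With 44 loci counted in withaferin A libraries of 340 to 430 counts, such correlations cannot show whether the replicate numbers pair the libraries. The depth of the withaferin A libraries limits every comparison above to loci over about 0.253% of counts.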

Other observations

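Tests of carry-over, of dilution, of counting error and of the kits against the totals were chosen after the results were seen, and the others before the data were examined. Neighbouring hairpins of 1 host gene had different values. miR-100-5p and the chromosome 11 copy of let-7a-5p both come from introns of MIR100HG, at 122152229 to 122152308 and 122146522 to 122146593, and had 1 and 232 counts after withaferin A against 3.96% and 3.34% of untreated counts. let-7a-5p is also made from other copies, so its counts are not those of this host alone. The miR-320 loci show how shared reads enter the table: in withaferin A replicate 3 miR-320a-5p, miR-320b, both copies of miR-320c and each of the 3 copies of miR-320d had exactly 1 count, so the 1188 counts stand for fewer reads.

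The first pattern is the low total of the withaferin A libraries. Reads carried over from the untreated libraries would keep the untreated composition. So would a shallow sample of the untreated RNA made with the same kit. miR-21-5p then should have had 349 counts and had 29, so at most 11.9% (upper 95% limit) of withaferin A counts can have either origin. A shallow sample of that RNA made with another kit need not keep the composition, and these counts cannot exclude it. The kit stays open. Read in the order the protocol gives, 0 groups held libraries of both kits. The kit then cannot be told apart from withaferin A, whose effect on yield was not tested. Trimming or counting set for 1 kit and used for both would make the totals a loss in processing, and no table bears on that.

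The second pattern is the number of loci called in edgeR (53). Of these calls, 24 lay outside counting error of the untreated share in the direction of the call (exact binomial test, adjusted p under 0.05 over the 303 loci). This argues against depth as their cause. The 24 include gene copies that share reads, such as those of miR-26a-5p, and so stand for fewer miRNAs. For the other 29 calls, with a median of 4.30 expected counts, depth cannot be told apart from a change. With every library thinned to 340 counts, only 3 to 5 of the calls were still tested, and 87.7% of them stayed called over 20 draws (67% to 100%), too few to decide. The 10 splits of the 6 libraries are too few for a share under 0.05. The real split gave 53 calls, and splits that mixed untreated and withaferin A libraries gave up to 65, 62 and 61. With the real split included, 4 of the 10 gave at least 53.

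The third pattern is the set of log2 fold changes. miR-205-5p, let-7a-5p and let-7c-5p went from 14.4% to 79.7% of counts, which alone would make every other locus 4.22-fold lower. let-7a-5p was summed over its copies, and its reads appear at each, so these shares and the factor are overstated. Of the 48 other loci above the floor, 20.8% (10, of which 4 lower and 6 higher) had an exact 95% interval that left this factor out. The lower were miR-21-5p, miR-100-5p, miR-148a-3p and miR-148a-5p, and the higher let-7e-5p, let-7f-5p, let-7i-5p, miR-125a-5p and each copy of miR-125b-5p. The 95% limits of that share, 10.5% to 35%, treat the 10 loci as independent, though they carry 9 names. These loci argue against such dilution as the whole cause. Leaving out the 10 most abundant loci kept 100% of the 46 other calls in the same direction, but it moved their median only from −14.34 to −14.33, and so shows nothing on how far a few abundant loci shaped the calls, which stays open. A kit that ligates each sequence with its own efficiency would make members of 1 cluster differ like random pairs; the median difference of 38 cluster pairs lay at the 38.2nd percentile of matched draws, but only 4 pairs had both members counted, so kit and withaferin A cannot be told apart, and a biological change stays open as untested. The differing ratios of let-7a-5p to let-7f-5p, which are close in sequence, may be a case for repeating both groups with 1 kit.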
